A study of Macaca mulatta with 13 samples.

How the data were processed

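Total RNA was extracted with Trizol and biotin-labelled cRNA was hybridised to one-colour Affymetrix arrays, per the labels' protocols. The deposited values are intensity values, 1 signal per probe set and array on a linear scale, which the authors summarised with MAS5, per the submitters' processing notes. The MAS5 version is not given in the sources used here. The 2% trimmed mean of the deposited intensity values was 500 on each of the 13 arrays, so the arrays carried 1 scaling factor each and no further normalization between arrays was seen. MAS5 detection calls were not used here. Samples were grouped by diet as the labels give it, 5 control and 8 CR monkeys, and each array is a separate animal per the labels. No column was left without a sample.

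The table held 52865 probe sets, of which 99 control probe sets were removed. Signals were set to a floor of 1, which applied to 137 values, and log2 transformed. The dimmer 50% of probe sets by mean log2 signal over all arrays were left out, which left 26383 with a mean signal of at least 107. Genes were named from the platform annotation: 24969 probe sets had 1 gene symbol, 361 had several and were not named, and 27535 had none listed. The 15770 tested probe sets with 1 symbol covered 9812 genes. For gene lists, each gene was represented by its brightest probe set. MAS5 scaling sets the trimmed mean of each array alike, so a shift of most transcripts in an animal would not be seen, and dim probe sets have a large spread on the log2 scale. The median residual SD was 0.45 on the log2 scale.

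Each probe set was compared between diets with lmFit and eBayes (trend) in limma 3.58.1 under R 4.3.3, two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The 32 gene lists of pathways, fibre types and cell types were fixed before the data were examined, as were the main tests and most alternatives. Lists were tested with camera at a preset correlation of 0.01, then with an estimated correlation and with fry, each adjusted over the 32 lists. A score per animal, the mean z score of a list's members, was compared by an exact two-sided permutation test over the 1287 splits of 13 animals. Named genes were the 10 genes with the lowest p in each direction, up to 4 members by p in the list's direction for each list past camera, and a set of metabolic and muscle genes fixed beforehand. Figures were drawn with matplotlib 3.10.9.

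The tests were checked on simulated data with the real means and spreads. Of 26383 simulated probe sets, limma's test recovered 10 of 67 changed by 1.5-fold, 21 of 67 changed by 2-fold and 50 of 66 changed by 4-fold, with 4 false calls. For 4 simulated lists shifted by 0.5 on the log2 scale, with genes drawn as independent, camera recovered 4 and the exact permutation test 3, with 0 false calls.

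Alternatives covered quantile normalization, median centring, an offset of 16, no filter, the brightest 25% of probe sets, eBayes without the trend, array quality weights, and the 3-prime over 5-prime ratios of the GAPDH and actin control probe sets as covariates. Further ones were 1 probe set per gene, the mean of a gene's probe sets, an exact rank-sum test, the replicate number as a block, and each animal left out in turn. CR replicates 6, 7 and 8 have numbers that no control has, so with the replicate block they add nothing to the diet difference. The first principal component as a covariate, control replicate 4 and CR replicate 8 left out together, and an estimated correlation in camera under the other alternatives or with an animal left out were chosen after seeing the data. The GAPDH ratio was 0.58 ± 0.23 (log2, SD, n = 5) in controls and 0.71 ± 0.13 (SD, n = 8) in CR, with p = 0.214 in an exact permutation test. The actin ratio was 1.74 ± 0.38 in controls and 1.74 ± 0.31 in CR, with p = 0.986 in the same exact test. No date or batch of the arrays is given in the sources used here, and ages are known per group only.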

Results

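Transcript levels were measured in the vastus lateralis, the large lateral muscle of the thigh, of 13 aged male rhesus monkeys (Macaca mulatta). The comparison asked which transcripts differ after long-term calorie restriction (CR), a diet with fewer calories than the control diet. There were 5 control animals of 27 to 30 years and 8 CR animals of 27 to 32 years, and the duration given for the restriction was 18.5 years. Each animal gave 1 one-colour Affymetrix array, so the number of arrays sets the precision. The arrays carried the same 2% trimmed mean signal of 500, and pairs of arrays correlated with r from 0.834 to 0.940 across the 26383 probe sets tested, which are not independent replicates.

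No probe set passed the test between the diets. With limma's moderated test on log2 signals and Benjamini-Hochberg adjustment, 0 probe sets were higher and 0 were lower in CR. At an unadjusted p under 0.05 there were 330 higher and 311 lower probe sets, together 2.43% of those tested, where chance gives 1319. The exact rank-sum test gave 2.48% at an unadjusted p under 0.05 and 0 after adjustment, but that 0 says little. With so few animals the smallest p of the rank-sum test is reached only where the groups do not overlap. Too few probe sets reached it for any to pass the adjustment. The groups did not overlap for 19 probe sets, where chance gives 41.0 (0.155%). The median half-width of the 95% interval of a difference, before adjustment, was 0.55 on the log2 scale. The adjusted threshold is stricter: in the simulated data 10 of 67 probe sets changed by 1.5-fold and 21 of 67 changed by 2-fold were recovered. Differences larger than 0.55 could thus also be missed with these arrays.

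The gene with the lowest p was ODAD3, which encodes a docking subunit of the outer dynein arms of motile cilia. Its signal was 5.91-fold higher in CR (log2 difference 2.56 ± 0.42 SE), and 8 of 8 CR animals lay above the control mean, but limma's adjusted p was 0.363. Its mean signal of 132 was close to the limit of 107 below which probe sets were not tested. Without control replicate 1 its log2 difference was 2.96, with an adjusted p of 0.0223 from limma. The next lowest adjusted p of a probe set in limma's test was 0.999.

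Among the other genes with the lowest p and a higher signal in CR, none passed. LXN, encoding the carboxypeptidase inhibitor latexin, differed by 1.74 ± 0.45 (SE, log2), and its other probe sets lay between -0.65 and -0.38. Without control replicate 5 the LXN difference was 2.31, with an adjusted p of 0.0382 from limma. HOMER1, a scaffold protein also found at the sarcomere, had a 2.83-fold higher signal (SE 0.45 on the log2 scale), while its other probe sets differed by 0.081 and 0.23. IL6R, the interleukin-6 receptor subunit, differed by 0.78 ± 0.23, and its other probe set by 0.11. GAS6, a ligand of the TYRO3, AXL and MERTK receptor kinases, differed by 0.58 ± 0.16, and its other probe set by -0.73. The values were 0.89 for DCAF8 (other probe sets 0.071 to 0.26), 0.70 for INPP4A (0.022 to 0.51), 1.09 for ZBTB43 (-0.0042 to 0.35), 1.44 for LOC696420 and 0.75 for NECTIN1.

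Among the genes with the lowest p and a lower signal in CR, none passed either. NNMT, which methylates nicotinamide, differed by -1.42 ± 0.46 (SE, log2), with an SD of 0.21 among controls and 1.06 among CR animals. ST14, encoding the membrane protease matriptase, differed by -1.22 ± 0.39 (other probe sets -0.32 and -0.30), and PRR32 by -1.04 ± 0.32. NADK2, the mitochondrial NAD kinase, differed by -0.67 ± 0.20, but its other probe sets by -0.22 and 0.24. ZMYND8, a chromatin reader, differed by -0.89 ± 0.26, with a further probe set at -0.80. GNG11, a G protein gamma subunit, differed by -0.65 ± 0.19, and its other probe set by -0.65. The values were -0.64 for APBB2 (other probe sets -0.63 to -0.50), -0.70 for IGSF8 (-0.25 and -0.023) and -0.59 for XPR1 (-0.12 to 1.01). A dim probe set of NDUFA10, a complex I subunit, differed by -0.75, while its brighter one differed by 0.26.

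**Figure D1:**
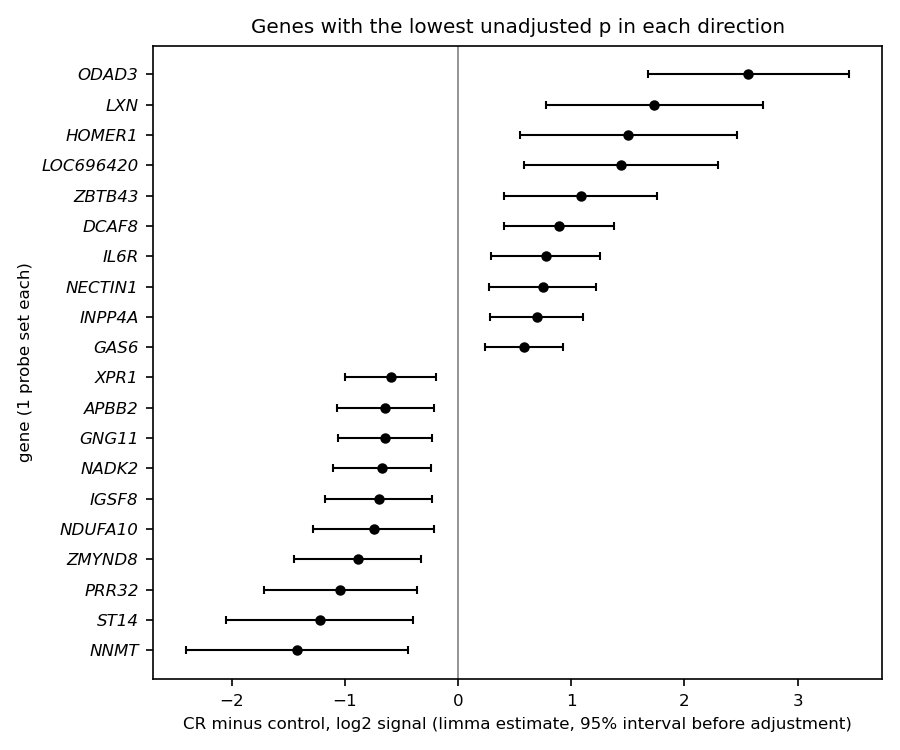
The horizontal axis gives the CR minus control difference in log2 signal and the vertical axis the 20 genes with the lowest unadjusted p, 10 in each direction. Points are limma's estimates and bars their 95% intervals before adjustment for the number of probe sets. ODAD3 has the largest difference, 2.56, and none of the 20 passed the adjusted threshold.

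Of the 32 gene lists fixed before the data were examined, 5 passed camera, which compares a list's genes with all others, at its preset correlation of 0.01 between genes. The lists of oxidative phosphorylation, glycolysis and glycogen, proteasome, and heat shock and protein folding were higher in CR, and the list of endothelium, pericytes and smooth muscle was lower. With the correlation estimated from the data, 0 lists passed and the adjusted p was 0.746 for each of the 5. In an exact two-sided permutation test of list scores per animal 0 lists passed (lowest p = 0.0715, adjusted p = 0.835). The smallest p the 1287 splits allow is 0.000777. The fry test also gave 0 lists. No member of any list passed, over all probe sets or adjusted over the list alone.

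Oxidative phosphorylation genes, which encode the respiratory chain and ATP synthase, had a mean log2 difference of 0.14, and 47 of 54 measured members were higher in CR (camera adjusted p = 0.000207, and adjusted p = 0.746 with an estimated correlation). NDUFC1 differed by 0.31 ± 0.21 (SE, log2), UQCRQ by 0.29 ± 0.21 and NDUFA13 by 0.29 ± 0.21. None passed limma's test. The direction of this list rested on control replicate 4, whose list score was -1.87 while the other controls lay between -0.61 and 0.93. Without that animal the mean was -0.016 with an adjusted camera p of 0.821. The camera call was also lost with the RNA quality ratios as covariates (mean 0.045, adjusted p = 0.291), with array quality weights (0.059, adjusted p = 0.144) and with the replicate block (0.068, adjusted p = 0.169).

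Glycolysis and glycogen genes had a mean log2 difference of 0.16, with 17 of 21 members higher in CR (camera adjusted p = 0.0177, and adjusted p = 0.746 with an estimated correlation). PHKB, a subunit of phosphorylase kinase, differed by 0.39 ± 0.18 (SE, log2), GAPDH by 0.33 ± 0.22, the aldolase gene ALDOA by 0.29 ± 0.21 and the hexokinase gene HK1 by 0.25 ± 0.18. None passed. Control replicate 4 had the lowest score here too, -1.37, and without it the mean was 0.011 with an adjusted camera p of 0.817. The camera call was also lost under several other settings, quantile normalization among them (adjusted p = 0.129).

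Proteasome genes, which encode subunits of the protease that degrades ubiquitin-tagged proteins, had a mean log2 difference of 0.18, with 21 of 23 members higher in CR (camera adjusted p = 4.45e-05, and adjusted p = 0.746 with an estimated correlation). PSMC4 differed by 0.41 ± 0.17 (SE, log2) but its other probe sets by -0.023 and 0.12, PSMB5 by 0.33 ± 0.20, PSMA7 by 0.32 ± 0.16 and PSMD6 by 0.31 ± 0.17. None passed. The list score was -0.38 ± 0.67 (SD, n = 5) in controls and 0.24 ± 0.53 (SD, n = 8) in CR, with p = 0.0940 in the exact permutation test. Control replicate 4 had the lowest score, -1.52, and without it the mean was 0.096 with an adjusted camera p of 0.0434, or 0.961 with an estimated correlation.

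Heat shock and protein folding genes had a mean log2 difference of 0.19, with 20 of 24 members higher in CR (camera adjusted p = 0.000207, and adjusted p = 0.746 with an estimated correlation). The chaperone gene HSP90AB1 differed by 0.59 ± 0.21 (SE, log2), DDIT3, a transcription factor of the unfolded protein response, by 0.46 ± 0.17, HSPH1 by 0.33 ± 0.18 and CCT5 by 0.26 ± 0.15. None passed. The list score was -0.31 ± 0.58 (SD, n = 5) in controls and 0.19 ± 0.37 (SD, n = 8) in CR, with p = 0.0715 in the exact permutation test. Without control replicate 4 the mean was 0.10 and the adjusted camera p 0.0614. Before adjustment the exact permutation p was 0.257 without control replicate 4 and 0.00505 without CR replicate 2.

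Markers of endothelium, pericytes and smooth muscle had a mean log2 difference of -0.31, with 17 of 18 members lower in CR (camera adjusted p = 0.00102, and adjusted p = 0.746 with an estimated correlation). The tight junction gene CLDN5 differed by -1.01 ± 0.52 (SE, log2), PECAM1 by -0.54 ± 0.32, the endothelial nitric oxide synthase gene NOS3 by -0.52 ± 0.32 and VWF by -0.50 ± 0.29. None passed, and the difference was -0.25 for PECAM1 and -0.24 for VWF without control replicate 4, and -0.30 for NOS3 without CR replicate 4. Control replicate 4 had the highest score, 1.41, and without it the mean was -0.12 with an adjusted camera p of 0.484. Without control replicate 5, with a score of 0.77, the mean was -0.23 and the adjusted camera p 0.0710.

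**Figure D2:**
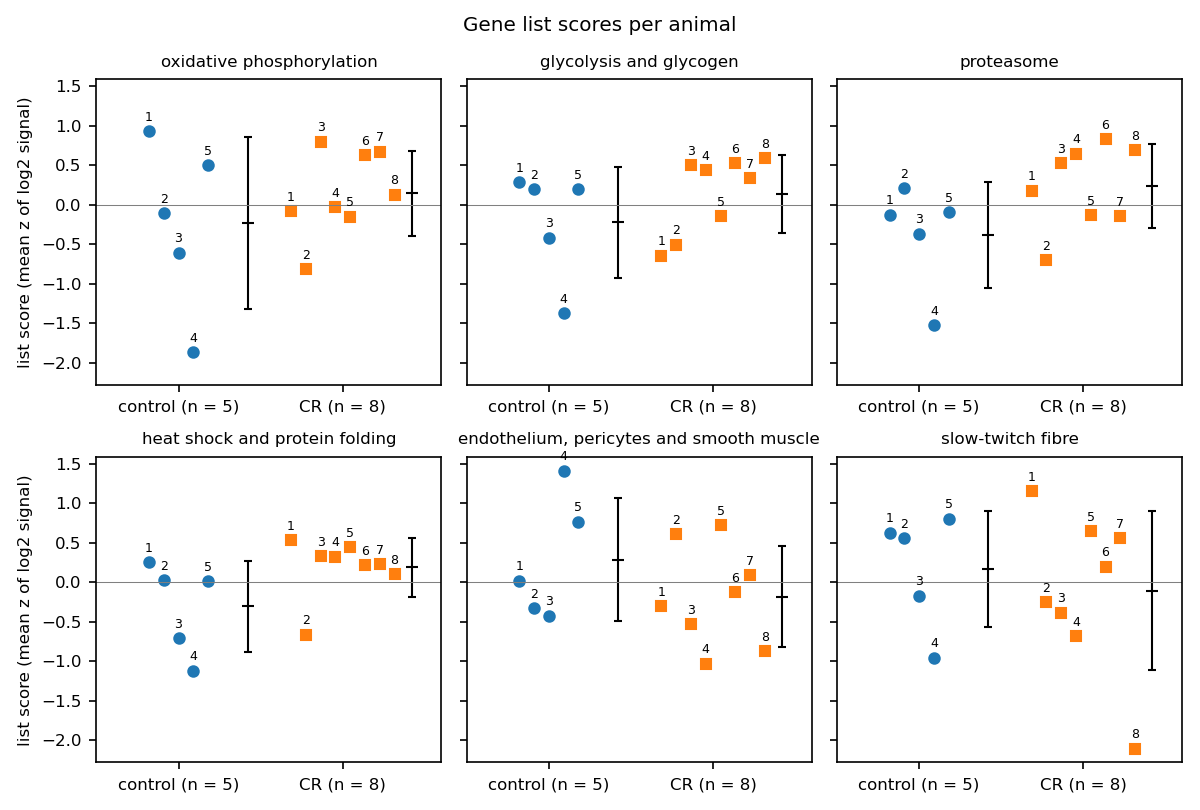
Each panel shows 1 gene list, with the list score (mean z score of the members' log2 signals) on the vertical axis and the diets on the horizontal axis. Circles are the 5 controls and squares the 8 CR animals, numbered by replicate, and black bars are the group mean and SD. Control replicate 4 lies at -1.87 for oxidative phosphorylation and at 1.41 for endothelium, and CR replicate 8 at -2.10 for slow-twitch fibre.

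The remaining lists did not pass camera at the preset correlation, and their values are mean log2 differences with camera's adjusted p. Fibre-type lists gave -0.45 for slow-twitch fibre (adjusted p = 0.0833) and 0.093 for fast-twitch fibre (adjusted p = 0.0690). Both moved with single animals. The slow-twitch mean was -0.79 without control replicate 4, where the list passed camera at the preset correlation but not with an estimated one (adjusted p = 0.961), and -0.076 without CR replicate 8 (adjusted p = 0.929). With both of these animals left out it was -0.41, and the list passed camera (adjusted p = 0.0116, and 0.985 with an estimated correlation). The fast-twitch mean ran from -0.0035 without control replicate 4 to 0.24 without CR replicate 1, where the list passed camera (adjusted p = 0.000376, and 0.784 with an estimated correlation). Fatty acid uptake and oxidation gave -0.076 (adjusted p = 0.325), and -0.18 without control replicate 4, where it passed camera (adjusted p = 0.00649, and 0.961 with an estimated correlation). The TCA cycle gave -0.0019 (adjusted p = 0.820), with a median of 0.10, so that its mean and median differed in sign. Mitochondrial ribosomal proteins gave 0.074 (adjusted p = 0.0690), mitochondrial biogenesis regulators -0.041 with a median of 0.00036 (adjusted p = 0.820), and insulin signalling 0.074 (adjusted p = 0.325).

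Lists of other cell types were also below the threshold. Adipocyte markers gave -0.40 (adjusted p = 0.0977), extracellular matrix and fibroblasts -0.17 (adjusted p = 0.0833), blood -0.37 (adjusted p = 0.205), and lymphocytes 0.22 over 6 measured members (adjusted p = 0.173). Without control replicate 4 the adipocyte mean was -0.043 and the matrix mean 0.022, with camera's direction turned for both (adjusted p = 0.996 and 0.817). Without control replicate 5 the matrix mean was -0.38, where the list passed camera (adjusted p = 3.96e-05, and 0.776 with an estimated correlation). The blood mean was -0.12 without control replicate 5 and -0.80 without control replicate 2, where the list passed camera (adjusted p = 0.00661, and 0.717 with an estimated correlation). Macrophages and myeloid cells gave 0.013 with a median of -0.034 (adjusted p = 0.963). Schwann cells and nerve gave -0.018 with a median of 0.040 and an upward camera direction (adjusted p = 0.820). Denervation and neuromuscular junction gave -0.090 (adjusted p = 0.334), muscle regeneration and satellite cells -0.18 (adjusted p = 0.657), and growth factor and myostatin signalling -0.033 (adjusted p = 0.648).

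Among stress and turnover lists, muscle atrophy and FOXO targets gave 0.055 (adjusted p = 0.303), antioxidant defence 0.043 (adjusted p = 0.380), and autophagy and mitophagy -0.0040 with a median of 0.012 (adjusted p = 0.963). The list of p53, senescence and cell cycle arrest gave -0.090 (adjusted p = 0.334) and immediate-early genes 0.17 (adjusted p = 0.334). Cytosolic ribosomal proteins gave 0.050 (adjusted p = 0.143), RNA splicing -0.047 (adjusted p = 0.334) and chromatin remodelling -0.034 (adjusted p = 0.599). The circadian clock gave -0.050 (adjusted p = 0.648), interferon and cytokine response -0.087 (adjusted p = 0.326), and lipid and cholesterol synthesis -0.14 (adjusted p = 0.198).

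The single genes chosen beforehand for their roles in muscle metabolism also did not pass limma's test. PPARGC1A, a coactivator of mitochondrial biogenesis, differed by 0.31 ± 0.32 (SE, log2), and TFAM, which maintains mitochondrial DNA, by -0.0066 ± 0.16, with its other probe sets from -0.25 to 0.42. SIRT1, a NAD-dependent deacetylase, differed by 0.17 ± 0.22. PDK4, which inhibits pyruvate dehydrogenase, differed by -0.51 ± 0.41 and the uncoupling protein gene UCP3 by 0.46 ± 0.37. The glucose transporter gene SLC2A4 differed by 0.24 ± 0.32, and by -0.17 without control replicate 4. Single animals moved several of these values. Without control replicate 4 the difference was 0.091 for PPARGC1A and 0.17 for UCP3, without control replicate 1 it was -0.16 for PDK4, and without control replicate 5 it was 0.0095 for SIRT1. TRIM63, a muscle ubiquitin ligase, differed by 0.47 ± 0.20, and FBXO32, another one, by 0.085 ± 0.24, or -0.067 without control replicate 4, and its other probe sets from -0.15 to 0.37. MYH2 differed by -0.065 ± 0.20, IGF1 by 0.027 ± 0.36 (other probe sets -0.27 to -0.0091), FOXO1 by -0.24 ± 0.28 and CHRNA1, an acetylcholine receptor subunit, by -0.85 ± 0.48. The adipokine genes gave -0.87 ± 0.96 for LEP (other probe set -0.20) and 0.13 ± 0.27 for ADIPOQ (-0.58 to 0.10). The IGF1 difference turned to -0.013 and the TFAM difference to 0.013 after quantile normalization. SIRT3, MYH7, MYH1 and MSTN were not analysed here, because no probe set carried their names in the annotation used.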

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

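The tests of control replicate 4, RNA quality, mature fibre genes and CR replicate 8 were chosen after the results were seen, while the counts of other splits were planned before them. Within each diet, samples far from the rest of their group were sought over 32 list scores and the named probe sets. This gave 11 flags in 172 groups, where chance flags about 1 in 20, or 8.60, so their number is no more than slightly above chance.

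Control replicate 4 stood apart for 5 named genes. Among controls it had the highest log2 signal of GNG11, 10.88, and of CLDN5, 9.27, and the lowest of UQCRQ, 14.41, HK1, 12.41, and PSMD6, 11.82. CR replicate 2 had the lowest heat shock and protein folding score in its group, -0.67, and the highest score of p53, senescence and cell cycle arrest, 0.60. CR replicate 8 had the highest circadian clock score, 0.68, and the lowest log2 signal of NNMT, 3.84. The highest NECTIN1 signal in the group was 8.67 in CR replicate 6, and the lowest NOS3 signal 5.86 in CR replicate 4.

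The number of lists past camera was weighed first. Of 100 splits of the 13 animals, 68 gave 5 or more lists, with up to 14 in another split, so chance cannot be excluded for the count of 5. For an unadjusted p under 0.05, 91 of 100 splits gave 641 or more probe sets, with a median of 1098.5, so chance cannot be excluded here either. The highest other split gave 5199, several times the real count, which points to a structure of the samples other than diet, though no test compared it with what correlated genes alone give. For the adjusted threshold the real count of 0 is reached by 100 of 100 splits by construction, with up to 10 in another split, so this test says nothing.

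For the 5 lists, control replicate 4 alone and RNA quality were then considered. Without control replicate 4, 1 of the 5 lists kept its call, the proteasome list (adjusted p of 0.0434 from camera in limma), and its mean went from 0.18 to 0.096. With an estimated correlation in camera that call is lost too (adjusted p = 0.961). Fewer controls alone do not explain the lost calls. Without control replicate 1 or control replicate 2 the 5 lists kept their calls at the preset correlation. Without control replicate 3 only glycolysis lost its call, and without control replicate 5 only endothelium. Because the proteasome list kept its call at the preset correlation, whether control replicate 4 alone accounts for the 5 calls stays open. With RNA quality as covariates, 4 of the 5 lists kept their camera call at the preset correlation (adjusted p = 0.788 for each of them with an estimated one). Their means did not vanish, at 0.18 for proteasome, 0.14 for glycolysis, 0.14 for heat shock and -0.43 for endothelium. The mean of oxidative phosphorylation went from 0.14 to 0.045 (camera adjusted p = 0.291). Such calls were also frequent among the splits of the animals, so keeping one cannot decide the matter, and RNA quality stays open as a cause. An effect of diet stays open as well.

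In control replicate 4, mature fibre genes were lower and markers of fat and matrix higher than on the other 12 arrays. The median deviation was -0.64 for fast-twitch fibre and -0.85 for oxidative phosphorylation, and 1.77 for adipocytes and 1.01 for matrix and fibroblasts. A lower share of muscle fibre in the piece could give this, and 6 of the 7 lists of other cell types had a median above the mean of the other arrays. Of these, macrophages, at 0.64, and blood, at 0.66, lay within the range of the other arrays. The lymphocyte list, with 6 measured members, lay at -0.49, also within that range, which leaves the explanation open. The regeneration and denervation lists had a joint median 0.59 higher, above the 0.22 reached on any other array. They hold fibre genes but also genes of other cells, such as satellite cells, and were tested after this rise was seen. Their rise therefore cannot decide whether the share of fibre was lower. Of the RNA quality ratios, 1 of 2 was above all other arrays, actin at 2.41, so degraded RNA stays open too.

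In CR replicate 8, slow-twitch fibre transcripts had a median deviation of -3.28 from the other 12 arrays, and fast-twitch ones 0.51. Other lists lay below all other arrays too, adipocytes at -1.69, matrix and fibroblasts at -0.73 and endothelium at -0.79. Of the RNA quality ratios, 0 of 2 lay above those of the other arrays, at 0.76 for GAPDH and 1.86 for actin (log2). This argues against RNA more degraded than on all other arrays, but 2 control transcripts cannot exclude degraded RNA. A diet effect of this size shared by the CR animals is also argued against. The mean score was 0.18 in the other 7 CR animals and 0.17 in the controls (difference 0.0037 ± 0.41 SE), against -2.10 in CR replicate 8. The control mean includes control replicate 4, at -0.96. With both animals left out the list's mean log2 difference was -0.41, so a smaller shared effect is not excluded. No other explanation was tested.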

How the results depend on the processing

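The first principal component as covariate and the joint removal of control replicate 4 and CR replicate 8 were chosen after seeing the data, as was the estimated correlation under other alternatives or with an animal left out, and the other alternatives before. The count of probe sets past limma's adjusted threshold stayed at 0 in both directions under each alternative that left no animal out. Without control replicate 1 the higher count was 1, ODAD3, and without control replicate 5 it was 1, LXN, so these counts ran from 0 to 1 over the animals left out. The share of probe sets at an unadjusted p under 0.05 was 2.43% in the main setting, 1.47% with the replicate block, and 1.91% to 4.61% with 1 animal left out, highest without CR replicate 2. The number of lists past camera went from 5 to 9 with arrays centred on their median, to 9 with the upper 25 percent of signal only, to 3 with array quality weights, to 9 with the 3-prime over 5-prime ratios as covariates and to 0 with an estimated correlation. It ran from 4 to 10 with 1 animal left out, highest without CR replicate 7. The exact permutation test of list scores gave 0 lists under each alternative it was run with. With a control left out, alone or together with CR replicate 8, fewer splits remain and the smallest possible p is too large for 1 list alone to pass. The 0 says little in those settings. The replicate block rests on numbers that do not pair the animals: correlations of same-numbered animals ran from -0.203 to 0.0202, and 0 of 5 controls correlated best with their own number. It also takes CR replicates 6, 7 and 8, whose numbers no control has, out of the diet difference. Values with this block thus rest on fewer animals than the main setting.

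Of 699 values of the 27 lists not called, 75 turned direction and 51 passed camera, and of 1336 values of the 54 named probe sets, 35 turned and 2 passed. The 12 lists that passed in some setting were slow-twitch fibre in 11 settings, extracellular matrix in 7, adipocytes in 6, mitochondrial ribosomal proteins in 6, fast-twitch fibre in 5, cytosolic ribosomal proteins in 4, fatty acid oxidation in 4, blood in 3, circadian clock in 2, and macrophages, immediate-early genes and lipid synthesis in 1 each. These 51 passes are at the preset correlation, and 0 of them held with an estimated correlation in the same setting (lowest adjusted p = 0.157). Of 103 passes of the called lists, the main setting included, 0 held either (lowest adjusted p = 0.668). A turned value of a list not called, or of a named gene, was past the threshold in neither setting. A list's direction is camera's, which ranks it against other genes, so the mean log2 difference given can keep its sign. With quantile normalization between arrays, the call was lost for glycolysis 0.10. The direction turned in this setting for autophagy -0.0022, TFAM 0.013 and IGF1 -0.013. With arrays centred on their median, the direction turned for macrophages 0.052 and TFAM 0.033. With no filter on dim probe sets, the call was lost for glycolysis 0.15. It turned direction for autophagy -0.0040 and lymphocytes -0.087. With the upper 25 percent of signal only, the direction turned for autophagy 0.011 and macrophages -0.071. With array quality weights, the call was lost for oxidative phosphorylation 0.059, glycolysis 0.093 and endothelium -0.19. Turned directions were those of TCA cycle -0.040, regeneration -0.077, autophagy -0.017 and TFAM 0.0046. With the 3-prime over 5-prime ratios as covariates, the call was lost for oxidative phosphorylation 0.045. In the same setting direction turned for TCA cycle -0.059, denervation 0.011, autophagy -0.015, growth factor signalling 0.0092 and ADIPOQ -0.072. With the replicate block, the call was lost for oxidative phosphorylation 0.068 and glycolysis 0.038. Direction turned there for TCA cycle -0.034, mitochondrial biogenesis 0.033, fast-twitch fibre -0.084, autophagy -0.044, extracellular matrix -0.018 and growth factor signalling 0.023. With the mean of all probe sets of a gene, the call was lost for glycolysis 0.13. This setting also turned mitochondrial biogenesis -0.028, regeneration -0.14, autophagy -0.011, macrophages -0.0022, GAS6 -0.072, XPR1 0.10, NDUFA10 -0.25, TFAM 0.014, IGF1 -0.12 and ADIPOQ -0.12. With the first principal component as covariate, the call was lost for oxidative phosphorylation 0.0017, glycolysis 0.0071 and endothelium -0.18. Also turned were TCA cycle -0.071, insulin signalling 0.033, regeneration -0.020, autophagy -0.039, extracellular matrix 0.016, mitochondrial ribosomal proteins -0.0099, interferon response 0.026, growth factor signalling 0.053, SLC2A4 -0.071 and FBXO32 -0.013. With control replicate 4 and CR replicate 8 left out together, the call was lost for proteasome 0.077, endothelium -0.045 and heat shock 0.11. The values that turned were oxidative phosphorylation -0.0100, TCA cycle -0.030, glycolysis -0.026, insulin signalling 0.021, fast-twitch fibre -0.059, denervation 0.049, regeneration 0.10, muscle atrophy -0.031, autophagy -0.047, extracellular matrix 0.11, adipocytes 0.14, mitochondrial ribosomal proteins -0.021, interferon response 0.067, growth factor signalling 0.10, lipid synthesis 0.057, TFAM 0.0057, SLC2A4 -0.24, FBXO32 -0.093 and LEP 0.14. With an estimated correlation in camera, 0 lists passed and the means stayed the same by construction: oxidative phosphorylation 0.14, glycolysis 0.16, proteasome 0.18, endothelium -0.31 and heat shock 0.19.

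With each animal left out in turn, means ran from -0.016 to 0.24 for oxidative phosphorylation, -0.79 to -0.076 for slow-twitch fibre, -0.0035 to 0.24 for fast-twitch fibre, -0.80 to -0.12 for blood, -0.19 to 0.0021 for denervation, -0.18 to 0.013 for interferon response, -0.23 to 0.0091 for lipid synthesis, 0.11 to 0.29 for lymphocytes, -0.15 to -0.0096 for p53 and senescence, 0.016 to 0.073 for antioxidant defence, 0.018 to 0.080 for cytosolic ribosomal proteins, -0.056 to -0.012 for chromatin remodelling, 0.045 to 0.10 for insulin signalling, -0.077 to 0.075 for TCA cycle, -0.18 to 0.043 for fatty acid oxidation, 0.011 to 0.23 for glycolysis, -0.11 to 0.026 for mitochondrial biogenesis, -0.27 to 0.0039 for regeneration, -0.028 to 0.094 for muscle atrophy, 0.10 to 0.22 for proteasome, -0.029 to 0.014 for autophagy, -0.38 to 0.022 for extracellular matrix, -0.68 to -0.043 for adipocytes, -0.11 to 0.12 for macrophages, -0.42 to -0.12 for endothelium, -0.12 to 0.17 for Schwann cells, 0.10 to 0.25 for heat shock, -0.0092 to 0.12 for mitochondrial ribosomal proteins, -0.17 to 0.011 for circadian clock, 0.043 to 0.27 for immediate-early genes, -0.10 to 0.056 for growth factor signalling and -0.083 to -0.0017 for RNA splicing. Named genes ran from 0.091 to 0.58 for PPARGC1A, -0.72 to -0.25 for PECAM1, -0.69 to -0.24 for VWF, -0.64 to -0.30 for NOS3, 0.18 to 0.43 for NDUFC1, 0.11 to 0.39 for UQCRQ, 0.11 to 0.43 for NDUFA13, 0.11 to 0.40 for the brighter NDUFA10 probe set, 0.23 to 0.49 for PHKB, 0.17 to 0.40 for ALDOA, 0.21 to 0.38 for PSMA7, 0.20 to 0.41 for PSMD6, 0.15 to 0.43 for GAPDH, 0.10 to 0.30 for HK1, 0.17 to 0.47 for PSMB5, 0.0095 to 0.31 for SIRT1, -0.77 to -0.16 for PDK4, 0.17 to 0.69 for UCP3, -1.13 to -0.58 for CHRNA1, -1.53 to -0.32 for LEP, -0.10 to 0.063 for TFAM, -0.18 to 0.036 for MYH2, -0.17 to 0.45 for SLC2A4, -0.25 to 0.41 for IGF1, -0.44 to 0.046 for FOXO1, -0.067 to 0.29 for FBXO32 and -0.16 to 0.33 for ADIPOQ. The cause of these changes was not tested, apart from the smaller number of animals or genes that a setting leaves by construction. Dim probe sets, with the signal close to the filter's limit of 107, have the least signal over background.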

Other observations

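The relations tested below, and the genes named for single animals, were chosen after the values were seen. Several muscle fibre genes varied widely between animals of the same diet. Among the 20 named genes with the largest spread within diets and a mean signal of at least 1000, 6 belonged to the slow-twitch list. Of these, MYL3, TNNT1, TPM3, TNNI1 and CSRP3 were lowest in CR replicate 8 and CASQ2 in CR replicate 4, so 1 animal adds much to their spread. MYL3, a slow-twitch myosin light chain, ranged over 6.33 on the log2 scale, with the lowest signal in CR replicate 8 and the highest in CR replicate 7. TNNT1, the slow troponin T, ranged over 5.44, and MYH8, the perinatal myosin heavy chain, over 6.99, highest in control replicate 4 and lowest in CR replicate 8. PVALB, a calcium buffer of fast fibres, ranged over 6.81 and MYH4, the IIb myosin heavy chain, over 5.66. MAMU-AG, a major histocompatibility gene of a polymorphic family, ranged over 7.46, and HBA, a haemoglobin chain, over 4.55.

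In control replicate 4, most of 8 genes of fibre development and denervation were above the mean of the other 12 animals on the log2 scale. The deviations were 4.11 for MYH8, 3.37 for the embryonic myosin gene MYH3, 4.03 for the cardiac and fetal troponin gene TNNT2, 1.77 for RUNX1, 1.75 for CHRNA1, 1.59 for ACTC1 and 0.82 for CHRND, while MYF6 deviated by -0.27. Collagen genes deviated by 2.23 for COL1A1 and 2.06 for COL1A2. LEP deviated by 2.93 and FABP4 by 1.92, but ADIPOQ by 0.22. The creatine kinase gene CKM deviated by -0.74, the myoglobin gene MB by -0.94 and MYH2 by -0.47. In CR replicate 8, slow-fibre genes were far below the others: MYL3 by -4.79, CSRP3 by -4.53, TNNT1 by -4.22, TNNI1 by -3.94 and ATP2A2 by -3.80. In the same animal ACTN3 deviated by 1.02 and MYLK2 by 1.46, while MYH4 deviated by -0.68.

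One hypothesis was that animals with low oxidative phosphorylation scores have high denervation and neuromuscular junction scores, whatever their diet. Over 13 animals Pearson's r was -0.746 (permutation p = 0.00211, adjusted p = 0.00934 over 31 relations), and Spearman's rho was -0.797 (adjusted p = 0.0187). Without control replicate 4 and control replicate 1, the animals farthest from the median, r was -0.595. Within the 8 CR animals r was -0.481 with an exact permutation p of 0.232, so the relation was not shown within CR, and it was not tested within the 5 controls. These values are consistent with such a relation as a hypothesis, in data where no batch could be examined. Of the 31 relations of the oxidative phosphorylation score, 8 were positive and 3 negative at an adjusted permutation p of Pearson's r under 0.05. The closest were the TCA cycle (r = 0.934) and mitochondrial ribosomal proteins (r = 0.898). The list of p53, senescence and cell cycle arrest had r = -0.805 and RNA splicing r = -0.760, both farther from 0 than denervation. By Spearman's rho both were nearer to 0 than denervation, at -0.687 for p53 (adjusted permutation p = 0.0606) and -0.604 for RNA splicing (adjusted permutation p = 0.1145). Within the 8 CR animals 3 relations passed after adjustment of the exact permutation p, the TCA cycle (r = 0.902), blood (r = 0.886, but 0.399 over 13 animals) and chromatin remodelling (r = -0.883), and denervation was not among them.

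A second hypothesis was that fat within the piece goes with a low oxidative phosphorylation score. For the adipocyte list r was -0.497 (permutation p = 0.0860, adjusted p = 0.140) and rho -0.170, and without control replicate 4 r was -0.072. Within the 8 CR animals r was -0.422 with an exact permutation p of 0.295. The test cannot decide whether the scores are related.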
